A study of Caenorhabditis elegans with 18 samples.

How the data were processed

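RNA sequencing was carried out on whole Caenorhabditis elegans collected as early adults. Animals of 3 genotypes, the standard wild-type strain N2 (WT) and strains mutant for the nuclear hormone receptor genes nhr-45 (allele tm1307) or nhr-178 (allele gk1005), were grown from the first larval stage on Escherichia coli HT115 with the solvent DMSO or with 0.3 µM antimycin A, an inhibitor of respiratory complex III. Each of the 6 groups holds 3 libraries, 18 in all. Per the labels' protocols, synchrony came from an arrest of 18 hours as first-stage larvae, at least 1000 staged animals were collected for a sample, and total RNA was purified with a column kit. The series text calls the samples biological triplicates. Whether the libraries of a group came from separate cultures is not stated beyond that, so the p-values measure the spread between these samples.

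The values are the counts per gene that the authors deposited as one table. They are whole numbers that sum to a different total in each library. Per the submitters' processing notes, the tools were Bowtie2, RSEM, DESeq2 and R 3.6.3, with no role stated for each. The genome build, the gene annotation, the handling of reads that map to several genes and the use of strand are not given in the sources used here. Reads of near-identical genes could therefore be split in different ways, so single members of the msp, vit, hsp-16, F44E5.4 and F44E5.5, cyp-33C and ugt-1 and ugt-2 groups are uncertain. So are genes that overlap another counted gene, which among those named below are F46C5.1, T04D3.8, aqp-1, ceh-38, clec-190, col-71, col-97, col-142, cth-2, cyc-2.2, far-3, gst-4, lea-1, maoc-1, nhr-57, perm-2, pho-11, sod-3, sqt-3 and vit-2.

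All 18 columns matched a sample by title, and every gene in the table has a WormBase identifier. The table has 23368 genes, of which 23161 have a symbol in the reference used here and 23363 have a position in the WBcel235 annotation, joined by identifier alone. Positions are from that annotation and may differ from the authors' build. A count was present in at least 1 library for 19659 genes. Total counts ranged from 1772887 in replicate 2 of nhr-45 in antimycin to 9488037 in replicate 3 of WT in DMSO. Replicate 1 of WT in antimycin had 3143437. Counts of 3 over the libraries of a group were taken as the floor where a group had none, which is 0.119 to 0.193 in the scaled unit given below, and covers counting error only. Within groups the libraries differed by more than sampling noise, with a chi-square per degree of freedom of 6.25 to 20.9, so none was counted as a duplicate.

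Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on all 18 libraries, with 1 mean per group, 12 residual degrees of freedom, TMM scaling and the filterByExpr filter by group, which left 10981 genes. The biological coefficient of variation was 17.1%. Each adjusted p is a Benjamini-Hochberg value within 1 comparison, called below 0.05. An SE of a log2 fold change is its size over the square root of the test statistic F. Levels are counts scaled to equal library size with the TMM factors (CPM), as mean ± SD over 3 libraries. All tests are two-sided. The comparisons were antimycin against DMSO within each genotype, each mutant against WT within each treatment, and the interaction of each mutant with antimycin, which tests whether the response to antimycin differed from that of WT. Comparisons against the same WT libraries were simulated 20 times with unchanged mutants.

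Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over 47 lists within a comparison, and again with an estimated correlation and with fry. A list was tested if it had at least 3 genes. Some lists share genes. The hypodermis list shares col-10, col-12, col-13 and col-19 with the collagen list and dpy-7, rol-6 and sqt-3 with the moulting list. The lists cover detoxification and stress families, the respiratory chain and intermediary metabolism, and markers of tissues, germline and moulting; 1 more list, the genes of the mitochondrial genome, was not analysed here. Genes to be named were the 10 highest and 10 lowest by log2 fold change (5 and 5 for antimycin in the mutants and for the mutants within antimycin) among called genes with a mean of at least 5 CPM and groups that do not overlap, up to 4 called members of each list past camera, and, for the interactions, genes also called for antimycin in WT, the 10 with the most reduced and 5 with the most enlarged induction and 5 with the most reduced repression. Also named were nhr-45, nhr-178, hsp-6, hsp-60, gst-4, acdh-1, sod-3 and nhr-57. The text names part of this set. The groups, comparisons, tests, lists, rule for named genes and alternatives were fixed before the data were examined.

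The steps were tested on simulated counts with the means and library sizes of the 10981 genes. For the tests of single genes, changes were made only in genes with a mean of at least 5 CPM. Recovery of weaker genes was therefore not measured. For antimycin in WT, 16.0%, 77.3%, 100% and 100% of genes changed by a log2 of 0.5, 1, 2 and 3 were recovered, and 3.27% of the calls were false. For nhr-45 against WT in DMSO these were 17.9%, 82.5%, 100% and 100%, with 5.77% false. For the nhr-45 interaction they were 2.5%, 51.1%, 96.4% and 100%, with 3.52% false, and for the nhr-178 interaction 0%, 43.1%, 87.5% and 97.9%, with 4.20% false. A shift of 0.5 in the list of UDP-glucuronosyltransferases gave a camera adjusted p of 3.2e-08 for antimycin in WT, with 1 of 46 other lists past the threshold.

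The alternatives were the size factors of DESeq2 1.42.0 in place of TMM, no filter on low counts, a filter of 5 CPM in 3 libraries, a fold change of at least 2, the replicate number as a block, the Wald test of DESeq2, a fit of only the groups compared, and leaving out each library. Leaving out both shallow libraries (WT in antimycin replicate 1 and nhr-45 in antimycin replicate 2) was added after seeing the data. Where a list is given an adjusted p with an estimated correlation and no other alternative is named, that value was the highest over its alternatives and the only one past 0.05.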

Results

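Gene expression was measured in whole early adult C. elegans of 3 genotypes, each grown with DMSO or with 0.3 µM antimycin A, with 3 libraries in each of 6 groups. The comparisons ask which genes respond to inhibition of complex III, and whether that response needs the nuclear hormone receptors NHR-45 or NHR-178, which are ligand-regulated transcription factors. Total counts ranged from 4414172 to 9488037 in the DMSO libraries and from 1772887 to 8679509 in the antimycin libraries. The shallowest were nhr-45 in antimycin replicate 2, with the lowest of these totals, and WT in antimycin replicate 1 (3143437), called both shallow libraries below. On the first principal component, which held 42.3% of the variance, the nhr-45 libraries in antimycin stood apart from the other 15. The second, with 10.5%, parted the WT and nhr-178 libraries by treatment.

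**Figure D1:**
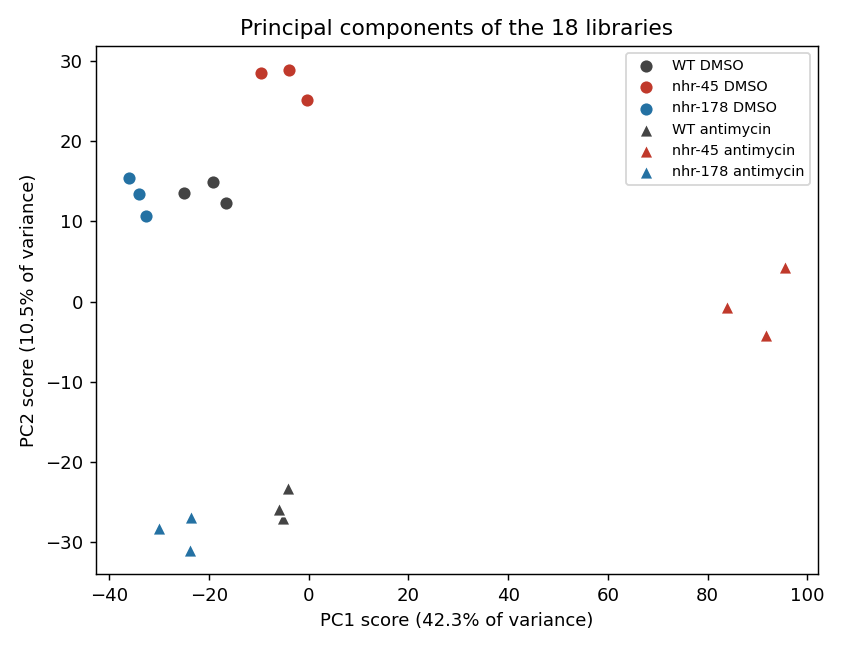
Scores of the 18 libraries on the first and second principal components of log2 CPM (circles, DMSO; triangles, antimycin; colour, genotype), which hold 42.3% and 10.5% of the variance. The 3 nhr-45 libraries in antimycin lie apart from all others on the first component.

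The targeted genes did not check the genotypes. nhr-45 (X:4656433-4660318) was counted at 5.88 ± 1.2 CPM in WT and 4.29 ± 1.34 CPM in the nhr-45 strain in DMSO, and at 7.19 ± 0.799 and 6.31 ± 1.38 CPM in antimycin (SD, n = 3 each), and it was called in no comparison. A deletion allele can leave transcript outside the deleted part, and counts per gene do not show which part was read. nhr-178 (V:1603906-1607953) had 6 counts over the 3 WT libraries in DMSO, 2 over the nhr-178 libraries in DMSO, 15 over WT in antimycin and 22 over nhr-178 in antimycin, too few to be tested.

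In WT animals, antimycin raised genes of xenobiotic metabolism. The UDP-glucuronosyltransferase gene ugt-9, whose family conjugates lipophilic compounds to sugars, was at 8.31 ± 1.74 CPM in DMSO and 1954 ± 220 CPM in antimycin (SD, n = 3), a log2 fold change of 7.88 ± 0.26 (SE, adjusted p = 2.3e-18). The cytochrome P450 gene cyp-33C5 rose by 7.89 ± 0.37 (adjusted p = 1.4e-14), from 0.720 ± 0.347 to 173 ± 30.1 CPM. F48G7.12, with no count in DMSO, was at least 177-fold higher in antimycin, against a floor of 3 counts over the group. cpr-1, a cathepsin B-like protease gene of the intestine, rose 8.81-fold. The acid phosphatase gene pho-11 fell by 1.53 ± 0.15 (adjusted p = 3.9e-08).

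Of 39 tested UDP-glucuronosyltransferases, 10 rose, 0 fell and 29 were not called by edgeR, while 14 rose adjusted over the list alone (camera adjusted p = 1.2e-26). ugt-61 rose by 5.96 ± 0.31 and ugt-62 by 3.71 ± 0.20. Of 32 cytochromes P450, 13 rose and 0 fell, against 14 and 1 adjusted over the list alone (camera adjusted p = 3.6e-17), with cyp-25A2 higher by 4.62 ± 0.29. Of 29 glutathione S-transferases, 7 rose and 0 fell, 9 adjusted over the list alone (camera adjusted p = 2.1e-10), with gst-33 higher by 5.70 ± 0.53 and gst-12 by 3.38 ± 0.30. Of 12 ABC exporters of the P-glycoprotein and MRP classes, 3 rose, also adjusted over the list alone (camera adjusted p = 0.000269, but adjusted p = 0.0576 with an estimated correlation and 0.0624 with no filter; range over the alternatives 2.4e-05 to 0.0624). Among them pgp-9 rose by 4.97 ± 0.37. Of 14 intestine markers, 3 rose and 5 adjusted over the list alone (camera adjusted p = 9.2e-09). Of 9 cytosolic heat shock genes, 4 rose, also adjusted over the list alone (camera adjusted p = 0.000108), with the small heat shock gene hsp-16.2 higher by 2.69 ± 0.32. Single libraries moved these counts: without WT in DMSO replicate 3 or WT in antimycin replicate 3, 7 and 8 cytochromes P450 rose, without WT in DMSO replicate 2 or WT in antimycin replicate 3, 1 ABC exporter and 1 intestine marker, without WT in DMSO replicate 3 also 1 intestine marker, and without WT in DMSO replicate 1 or WT in antimycin replicate 3, 2 heat shock genes.

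In WT, 20 of 98 cuticle collagens, which build the exoskeleton, rose and 4 fell, and 29 rose and 4 fell adjusted over the list alone (camera adjusted p = 3.8e-11). col-129 rose by 2.14 ± 0.17 and col-97 by 2.53 ± 0.29. Hypodermis markers passed camera (adjusted p = 0.00109), with 2 higher and 1 lower of 10, and 6 and 1 adjusted over the list alone (adjusted p = 0.0683 with an estimated correlation). Among 6 vitellogenins, the yolk proteins, 2 fell and 5 adjusted over the list alone (camera adjusted p = 3.6e-06, but adjusted p = 0.0576 with an estimated correlation). vit-3 was at 598 ± 118 CPM in DMSO and 280 ± 77.1 CPM in antimycin. Sperm genes had a median log2 change of 0.95 with 0 of 40 called by edgeR (10 at an unadjusted p under 0.05, 2 by DESeq2) and 5 higher adjusted over the list alone (camera adjusted p = 0.000603, but adjusted p = 0.256 with an estimated correlation). Oocyte and eggshell genes had a median of -0.25 with 1 of 19 lower and 6 adjusted over the list alone (camera adjusted p = 1.8e-05, but adjusted p = 0.0683 with an estimated correlation).

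Peroxisomal oxidation genes had 3 of 11 higher in WT, and 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0150, but adjusted p = 0.0683 with an estimated correlation). maoc-1, an enoyl-CoA hydratase of peroxisomal beta-oxidation, rose by 1.11 ± 0.17, and the acyl-CoA oxidase gene acox-3 by 2.22 ± 0.45. Without WT in DMSO replicate 3 that list's adjusted p was 0.0913 (range over the alternatives 0.00154 to 0.0913). Pathogen response genes had 1 of 19 lower and 3 adjusted over the list alone (camera adjusted p = 0.0297, but adjusted p = 0.157 with an estimated correlation). Their adjusted p was 0.0709 without WT in DMSO replicate 1, 0.173 without WT in antimycin replicate 1, 0.192 without both shallow libraries, 0.101 with no filter and 0.22 with the stricter filter (range over the alternatives 0.0113 to 0.22). The mitochondrial chaperone genes hsp-6 and hsp-60, common readouts of mitochondrial stress, had log2 changes of -0.08 ± 0.13 (adjusted p = 0.861) and -0.19 ± 0.12 (adjusted p = 0.478), and neither was called in any of the 9 comparisons.

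In all, edgeR called 330 genes for antimycin in WT, 227 higher and 103 lower, of which 193 changed at least 2-fold (153 higher, 40 lower). Without both shallow libraries it called 302. The count was 218, 183 and 202 without WT in DMSO replicates 1, 2 and 3, and 200 and 173 without WT in antimycin replicates 2 and 3.

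In nhr-45 animals, antimycin raised cuticle collagen, moulting and sperm genes and lowered yolk and oocyte genes. The collagen gene col-109 rose by 6.06 ± 0.27 (SE, adjusted p = 6.4e-15), from 5.79 ± 3.46 to 363 ± 55.5 CPM (SD, n = 3), and col-127, with no count in DMSO, was at least 99.3-fold higher in antimycin. The moulting gene mlt-8 rose by 4.90 ± 0.26 and the collagen gene sqt-3, needed for body shape, by 4.95 ± 0.44. The yolk gene vit-2 fell by 1.28 ± 0.18. M199.9 and the C-type lectin gene clec-190, neighbours on chromosome IV, fell by 2.89 ± 0.24 and 2.04 ± 0.17.

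Of the 98 collagens, 68 rose and 7 fell, with 71 and 9 adjusted over the list alone (camera adjusted p = 8.1e-65), and the median log2 change was 3.79. Of 16 moulting genes, 15 rose and 0 fell, with 15 and 1 adjusted over the list alone (camera adjusted p = 2.0e-15). Of 10 hypodermis markers, 7 rose and 0 fell, with 8 and 1 adjusted over the list alone (camera adjusted p = 1.8e-13). That list shares genes with the collagen and moulting lists, so its results here and below are not separate from theirs. Of 40 sperm genes, 38 rose, also adjusted over the list alone (camera adjusted p = 7.3e-23), with msp-59, a major sperm protein gene, higher by 3.42 ± 0.36. In the same libraries all 6 vitellogenins fell (camera adjusted p = 1.9e-10). So did 15 of 19 oocyte and eggshell genes, 18 adjusted over the list alone (camera adjusted p = 8.9e-09), among them the yolk receptor gene rme-2 by 0.74 ± 0.14 and perm-2 by 0.79 ± 0.12. Of 17 germline genes 6 fell, 9 adjusted over the list alone (camera adjusted p = 0.00122, but adjusted p = 0.0822 with an estimated correlation), and 1 fell without nhr-45 in DMSO replicate 1 and 3 without nhr-45 in antimycin replicate 1 or 3.

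Of the 14 intestine markers 7 rose in nhr-45, also adjusted over the list alone (camera adjusted p = 6.2e-05), with the intestinal filament gene ifb-2 higher by 1.65 ± 0.14 and cpr-1 by 1.81 ± 0.15. Of 9 genes of complex III and cytochrome c, 7 rose, also adjusted over the list alone (camera adjusted p = 0.0342, but adjusted p = 0.0853 with an estimated correlation and 0.0705 without nhr-45 in DMSO replicate 3; range over the alternatives 1.1e-06 to 0.0853). With no filter, or without nhr-45 in DMSO replicate 1 or 3 or nhr-45 in antimycin replicate 1, 4 of them rose, and 3 without nhr-45 in antimycin replicate 3. ucr-2.1 rose by 0.93 ± 0.16 and cyc-2.2, a cytochrome c gene, by 2.96 ± 0.59. Of 5 genes of the propionate shunt, a vitamin B12-independent breakdown route, 4 fell, also adjusted over the list alone (camera adjusted p = 0.00635, but adjusted p = 0.237 with an estimated correlation), where acdh-1 fell by 0.72 ± 0.16. The UDP-glucuronosyltransferases, cytochromes P450 and glutathione S-transferases did not pass camera in nhr-45. ugt-9 was at 6.52 ± 2.47 CPM in DMSO and 6.52 ± 2.74 CPM in antimycin.

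In all, 2585 genes were called for antimycin in nhr-45, 1670 higher and 915 lower, of which 1278 changed at least 2-fold. A fit of the compared groups alone called 1958, and the fit without both shallow libraries called 2271.

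**Figure D2:**
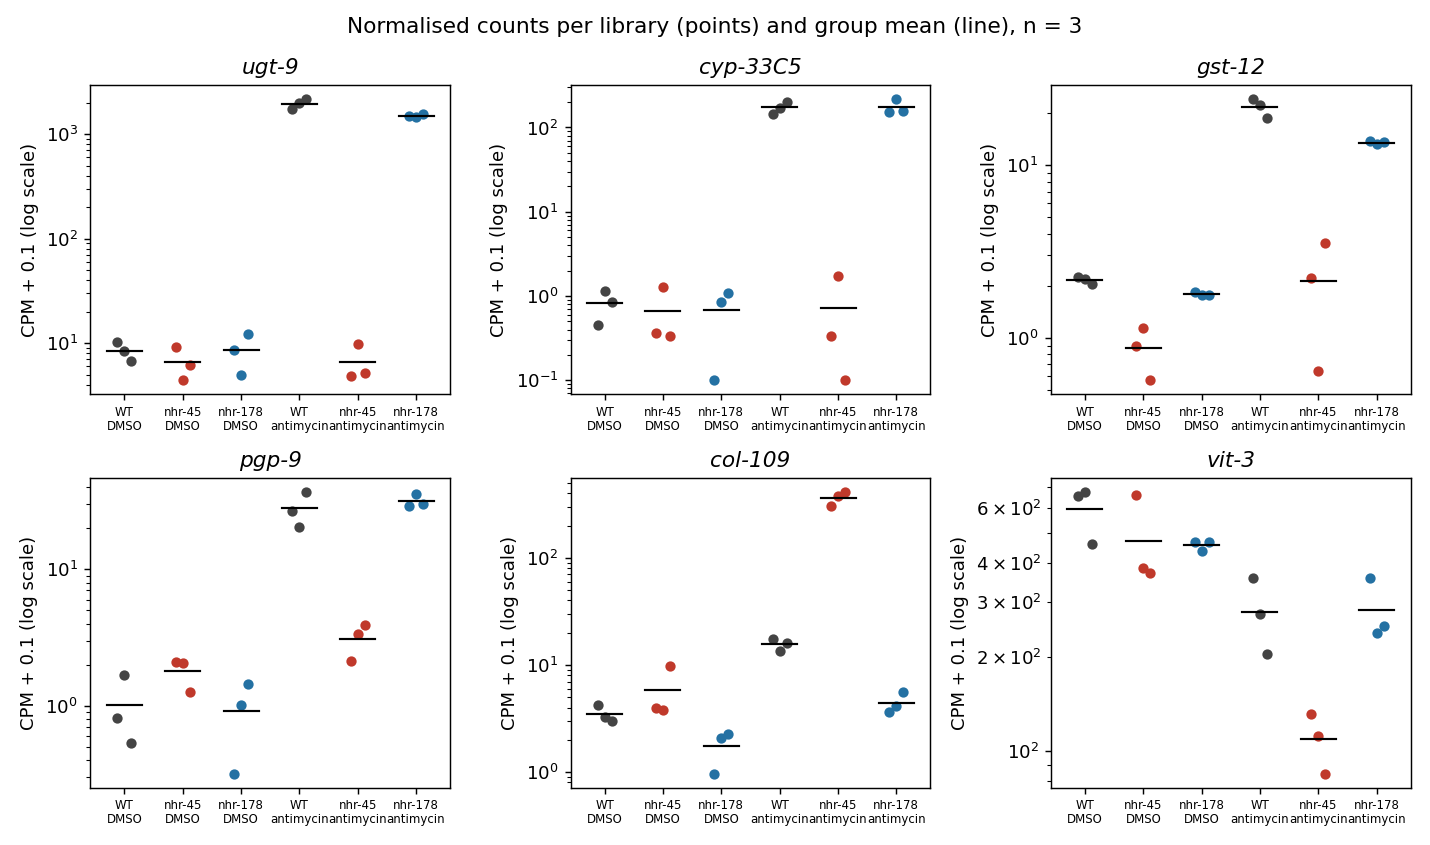
CPM of ugt-9, cyp-33C5, gst-12, pgp-9, col-109 and vit-3 in each library, plus 0.1, on log axes (points) with the group mean (line), n = 3 per group. ugt-9 and cyp-33C5 are at 1954 and 173 CPM in WT in antimycin and at 6.52 and 0.617 CPM in nhr-45 in antimycin, while col-109 is at 363 CPM in nhr-45 in antimycin.

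In nhr-178 animals, antimycin raised genes of xenobiotic metabolism, among them several named for WT. ugt-9 rose by 7.47 ± 0.26 (SE, adjusted p = 9.9e-18), from 8.49 ± 3.64 to 1495 ± 50.3 CPM (SD, n = 3), and cyp-33C5 by 8.07 ± 0.40 (adjusted p = 2.5e-14). F48G7.12, gst-33 and cyp-13A7 had no count in nhr-178 in DMSO and were at least 190-fold, 90.9-fold and 27.9-fold higher in antimycin. pgp-9 rose by 5.17 ± 0.39 and cpr-1 by 2.41 ± 0.15. The collagen gene col-10 fell by 2.60 ± 0.32 (adjusted p = 3.4e-06).

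Of 39 UDP-glucuronosyltransferases 11 rose, with 17 higher and 1 lower adjusted over the list alone (camera adjusted p = 7.2e-27). Of 32 cytochromes P450 13 rose, with 14 and 1 adjusted over the list alone (camera adjusted p = 5.7e-17). Of 29 glutathione S-transferases 8 rose, 9 adjusted over the list alone (camera adjusted p = 1.4e-12), and of 12 ABC exporters 3 rose, 4 adjusted over the list alone (camera adjusted p = 4.2e-05). Intestine markers rose in 5 of 14 cases, 7 adjusted over the list alone (camera adjusted p = 8.5e-10), and peroxisomal oxidation genes in 3 of 11, also adjusted over the list alone (camera adjusted p = 0.000149), with maoc-1 higher by 1.33 ± 0.17. Of the 5 propionate shunt genes 4 fell and 5 adjusted over the list alone (camera adjusted p = 1.0e-09), where acdh-1 fell by 0.79 ± 0.16 and hach-1 by 0.94 ± 0.13. Of these counts, 3 intestine markers rose without nhr-178 in DMSO replicate 2, 1 peroxisomal gene rose without nhr-178 in DMSO replicate 1 or 3 or nhr-178 in antimycin replicate 2, and 2 shunt genes fell without nhr-178 in DMSO replicate 1. Sperm genes had 2 of 40 higher, 6 adjusted over the list alone (camera adjusted p = 0.000227, but adjusted p = 0.305 with an estimated correlation), and a median log2 change of 1.83, or 0.68 with genes that had a group at 0 set to their bound. Cytosolic ribosomal proteins had a median of -0.11 with 0 of 77 called by edgeR (5 at an unadjusted p under 0.05, 0 by DESeq2), also adjusted over the list alone (camera adjusted p = 0.00723, but adjusted p = 0.515 with an estimated correlation and 0.113 without nhr-178 in DMSO replicate 1; range over the alternatives 0.000278 to 0.515). Oocyte and eggshell genes had a median of -0.18 with 0 of 19 called by edgeR, also adjusted over the list alone (3 at an unadjusted p under 0.05, 0 by DESeq2; camera adjusted p = 0.0479, but adjusted p = 0.401 with an estimated correlation). Their adjusted p was 0.160 without nhr-178 in DMSO replicate 1, 0.0635 and 0.134 without nhr-178 in antimycin replicates 2 and 3, 0.0503 with size factors and 0.0834 with the stricter filter (range over the alternatives 0.00578 to 0.401). With fry the adjusted p was 0.147 for the ribosomal proteins and 0.0747 for the oocyte and eggshell genes.

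In all, 297 genes were called for antimycin in nhr-178, 225 higher and 72 lower, and 203 changed at least 2-fold. The count was 196 without nhr-178 in antimycin replicate 3 and 311 without both shallow libraries, which belong to other groups.

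The responses can be set side by side because they share no library. Of the 227 genes called higher in WT, 53.3% were also called higher in nhr-45 (121 genes, against 34.5 for independent lists) and 45.8% in nhr-178 (against 4.65 genes for independent lists). Of genes called lower in WT, 30 were also called lower in nhr-45 (8.58) and 22 in nhr-178 (0.675). Across the 10981 genes, which are not independent replicates, the log2 changes of WT correlated with those of nhr-45 at r = 0.386 (jackknife SE over libraries 0.128; Spearman 0.321) and with those of nhr-178 at r = 0.417 (SE 0.111; Spearman 0.238). Those of both mutants correlated at 0.240 (SE 0.0999; Spearman 0.227). With no filter on low counts these correlations were 0.121, 0.121 and 0.0978, and that of WT and nhr-178 was 0.541 with the stricter filter and 0.853 over genes called in WT. The differences between these correlations were not tested.

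The interaction of nhr-45 with antimycin tests where the response differed from WT. The induction of ugt-9 was smaller in nhr-45 (interaction log2 -8.10, SE 0.39, n = 3 per group, adjusted p = 3.6e-14), that of cyp-33C5 gave -8.76 ± 1.16 (adjusted p = 1.8e-05), and that of the exporter gene pgp-9 gave -4.27 ± 0.59 (adjusted p = 3.5e-05). ugt-61, ugt-62, ugt-11 and cyp-25A2 gave -5.07 ± 0.81, -2.34 ± 0.30, -2.47 ± 0.38 and -4.97 ± 0.57. The fatty acid and retinol binding protein gene far-3 gave -2.63 ± 0.53. The response was more positive in nhr-45 for col-109 (3.89 ± 0.39), mlt-8 (3.95 ± 0.37) and F46C5.1 (4.52 ± 0.40, adjusted p = 1.8e-08). col-10, which fell in WT, gave 6.10 ± 0.47 (adjusted p = 9.5e-10).

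Of 153 genes induced at least 2-fold in WT, 27 had a smaller response in nhr-45 and 27 a larger one, against a mean of 0.05 smaller in simulations of an unchanged mutant. Among them, 7 of 10 UDP-glucuronosyltransferases had a smaller response and 0 a larger one, with a median log2 response of 3.38 in WT and 0.20 in nhr-45. Of 13 cytochromes P450, 3 had a smaller response. Their median was 4.28 in WT, or 3.92 with genes that had a group at 0 set to their bound. In nhr-45, 4 of the 13 had at most 3 counts in each group and so no fold change, and the other 9 had a median of -0.23. Of 7 glutathione S-transferases 0 had a smaller response, with medians of 2.02 and 1.13. In nhr-45, 2 of the 7 had at most 3 counts in each group and so no fold change. Antimycin was called to raise 2 of the 7 in nhr-45 and 7 in nhr-178, so the 0 does not show an unchanged induction. Of 19 induced collagens, 12 had a larger response and 1 a smaller one, with medians of 2.57 and 5.62. Of 40 genes repressed at least 2-fold in WT, 12 had a smaller repression or the opposite change. The last count was 7 without WT in DMSO replicate 1, WT in DMSO replicate 3 or WT in antimycin replicate 3, and 21 without both shallow libraries, with no filter or by DESeq2.

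By lists, the response of 7 of 39 UDP-glucuronosyltransferases was lower in nhr-45 than in WT, with 1 higher and 9 lower adjusted over the list alone (camera adjusted p = 1.4e-06, and 0.0718 with no filter; range over the alternatives 8.5e-08 to 0.0718). That of 33 of 98 collagens was higher and of 3 lower, with 42 and 7 adjusted over the list alone (camera adjusted p = 6.8e-19). Moulting genes were higher in 6 of 16 cases, 10 adjusted over the list alone (camera adjusted p = 3.4e-11), with sqt-3 at 3.82 ± 0.58, and hypodermis markers in 4 of 10 with 1 lower, 5 and 1 adjusted over the list alone (camera adjusted p = 6.3e-07). Cytochromes P450 were lower in 3 of 32 cases, 4 adjusted over the list alone (camera adjusted p = 0.000402, but adjusted p = 0.0551 with an estimated correlation). Sperm genes were higher in 4 of 40 cases, 14 adjusted over the list alone, vitellogenins lower in 3 of 6, 4 adjusted over the list alone, and the germline list lower in 1 of 17, also adjusted over the list alone. Their camera adjusted p of 6.3e-07, 0.000174 and 0.00445 became adjusted p = 0.127, 0.126 and 0.126 with an estimated correlation. Higher sperm genes numbered 2 without WT in DMSO replicate 1 or 3 and 8 with no filter. Lower vitellogenins numbered 0 without nhr-45 in DMSO replicate 1 or nhr-45 in antimycin replicate 3, 1 without nhr-45 in antimycin replicate 2 or without both shallow libraries, and 6 with no filter.

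More lists passed camera for this interaction with the preset correlation alone. DAF-16 readout genes had 4 of 8 higher, also adjusted over the list alone, among them aqp-1, an aquaglyceroporin gene, at 1.48 ± 0.32 (camera adjusted p = 0.00549, but adjusted p = 0.126 with an estimated correlation and 0.0616 without WT in DMSO replicate 2; range over the alternatives 0.000959 to 0.126). Pathogen response genes had 4 of 19 higher, 6 adjusted over the list alone, with irg-4 at 2.33 ± 0.45 (camera adjusted p = 0.00848, but adjusted p = 0.126 with an estimated correlation and 0.143 with the stricter filter; range over the alternatives 0.00144 to 0.143). Of these, 1 was called without WT in DMSO replicate 1, and 2 were called without WT in DMSO replicate 2, WT in antimycin replicate 2 or 3, nhr-45 in antimycin replicate 1 or both shallow libraries, or with the stricter filter. Propionate shunt genes had 1 of 5 lower, ech-6 at -0.89 ± 0.19, and 4 adjusted over the list alone (camera adjusted p = 0.00579, but adjusted p = 0.191 with an estimated correlation). Oocyte and eggshell genes had 0 of 19 called by edgeR (7 at an unadjusted p under 0.05, 1 by DESeq2), 2 lower adjusted over the list alone (camera adjusted p = 0.00258, but adjusted p = 0.163 with an estimated correlation), and heat shock genes 0 of 9, also adjusted over the list alone (3 at an unadjusted p under 0.05, 0 by DESeq2; camera adjusted p = 0.0268, but adjusted p = 0.127 with an estimated correlation).

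In total, 514 genes were called for the nhr-45 interaction, 372 higher and 142 lower, and 470 without both shallow libraries. The count was 335 without WT in DMSO replicate 3 and 336 without WT in antimycin replicate 3.

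**Figure D3:**
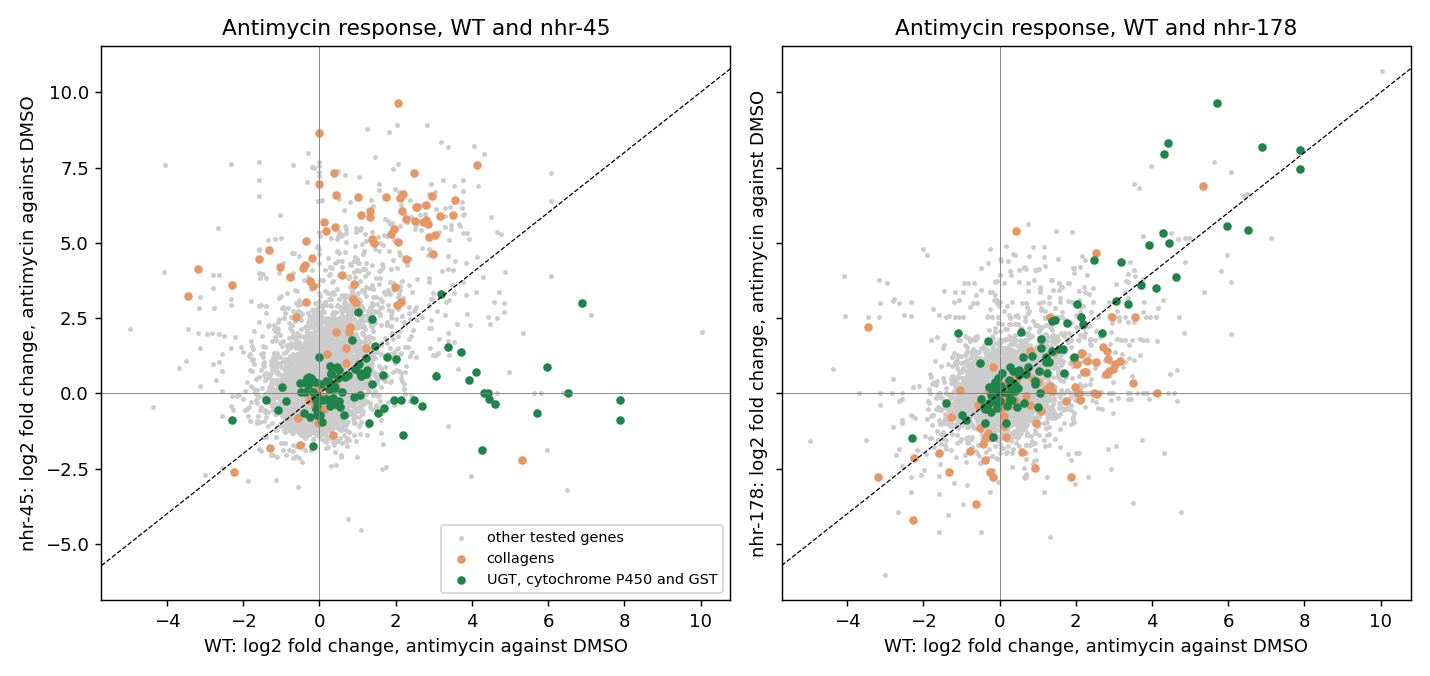
Log2 fold change to antimycin in WT (horizontal axis) against that in each mutant (vertical axis) for the 10981 tested genes, with the line of equal response. Colours mark the collagens and, together, the UDP-glucuronosyltransferases, cytochromes P450 and glutathione S-transferases. The 10 UDP-glucuronosyltransferases induced at least 2-fold in WT have a median of 3.38 in WT, 0.20 in nhr-45 and 3.28 in nhr-178.

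For nhr-178 fewer responses differed from WT. ram-2, a gene of ray morphology, gave an interaction of -3.36 ± 0.42 (SE, adjusted p = 0.000156, n = 3 per group), and the muscle myosin heavy chain gene unc-54 -1.41 ± 0.25 (adjusted p = 0.00917). F46C5.1 gave 3.13 ± 0.41 (adjusted p = 0.000222), the aspartic protease gene asp-8 1.4 ± 0.24 and T04D3.8 1.94 ± 0.33. Of the 153 genes induced in WT, 4 (ram-2, col-81, Y53F4B.9 and unc-54) had a smaller response in nhr-178 and 0 a larger one by edgeR, against a mean of 0 smaller in simulations and 16 smaller with no filter on low counts. By edgeR 0 of the induced UDP-glucuronosyltransferases, cytochromes P450, glutathione S-transferases and ABC exporters did either. Their median log2 responses in nhr-178 were 3.28, 4.93 (4.80 with groups at 0 set to their bound), 2.95 and 2.69. At an unadjusted p under 0.05 the interaction held 906 of the 10981 genes, and DESeq2 called 72 where edgeR called 29, or 103 with no filter. Of 40 repressed genes 2 (pho-11 and T04D3.8) had a smaller repression. The call of Y53F4B.9 (adjusted p = 0.0488) ended without any of the 12 libraries compared except replicate 1 of WT and of nhr-178 in antimycin (0.0740 to 0.236), and that of pho-11 (adjusted p = 0.0377) without any except WT in DMSO replicate 2 and WT in antimycin replicate 1 (0.0605 to 0.144).

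Collagens were lower by interaction in nhr-178 in 3 of 98 cases, 8 adjusted over the list alone (camera adjusted p = 9.9e-09). The 3 became 0 without WT in antimycin replicate 3 or nhr-178 in antimycin replicate 2, 1 without WT in DMSO replicate 2, nhr-178 in DMSO replicate 3 or nhr-178 in antimycin replicate 3, and 8 with no filter. Pathogen response genes had a median of 0.59 (0.40 with groups at 0 set to the floor) with 0 of 19 called by edgeR (6 at an unadjusted p under 0.05, 0 by DESeq2) and 3 higher adjusted over the list alone (camera adjusted p = 6.4e-05). Propionate shunt genes had 1 of 5 lower, 4 adjusted over the list alone (camera adjusted p = 1.8e-07, but adjusted p = 0.0536 with an estimated correlation). Cytosolic ribosomal proteins, sperm genes, lysosomal lipases, vitellogenins and hypodermis markers passed camera with adjusted p = 0.0372, 0.0372, 0.0448, 0.0448 and 0.0448 and 0 genes called by edgeR in each, also adjusted over the list alone, or by DESeq2, with 3, 8, 1, 1 and 3 genes at an unadjusted p under 0.05. These became adjusted p = 0.694, 0.577, 0.394, 0.547 and 0.394 with an estimated correlation. With fry they were 0.418, 0.382, 0.0898, 0.37 and 0.233. For the ribosomal proteins the adjusted p was 0.379 without WT in DMSO replicate 2, 0.314 without WT in antimycin replicate 1, 0.339 without nhr-178 in DMSO replicate 1 and 0.0545 and 0.112 without nhr-178 in antimycin replicates 1 and 3 (range over the alternatives 0.00473 to 0.694). For the sperm genes the adjusted p was 0.152 and 0.0811 without WT in DMSO replicates 1 and 3, 0.0583 and 0.11 without WT in antimycin replicates 1 and 3, 0.223 and 0.134 without nhr-178 in DMSO replicates 1 and 3 and 0.0998 and 0.273 without nhr-178 in antimycin replicates 1 and 2 (range over the alternatives 0.00585 to 0.577). For the lipases the adjusted p was 0.126 and 0.0811 without WT in DMSO replicates 1 and 3, 0.0583, 0.102 and 0.0767 without WT in antimycin replicates 1, 2 and 3, 0.0582 and 0.118 without nhr-178 in DMSO replicates 1 and 3 and 0.12, 0.0503 and 0.0534 without nhr-178 in antimycin replicates 1, 2 and 3 (range over the alternatives 0.0321 to 0.532). For the vitellogenins the adjusted p was 0.0914 without WT in DMSO replicate 3, 0.138 without WT in antimycin replicate 3, 0.206 without nhr-178 in DMSO replicate 2 and 0.186 without nhr-178 in antimycin replicate 1 (range over the alternatives 0.0193 to 0.547). For the hypodermis markers the adjusted p was 0.0622 and 0.0832 without WT in DMSO replicates 1 and 3, 0.215 and 0.11 without WT in antimycin replicates 1 and 3, 0.16 without nhr-178 in DMSO replicate 3 and 0.0545 and 0.26 without nhr-178 in antimycin replicates 1 and 2 (range over the alternatives 0.0098 to 0.394).

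The interaction of nhr-178 was called for 29 genes in all, 16 higher and 13 lower, for 43 without both shallow libraries and for 103 with no filter on low counts. The count was 15 and 18 without WT in DMSO replicates 1 and 2, 15, 16 and 19 without nhr-178 in DMSO replicates 1, 2 and 3, 16 and 11 without WT in antimycin replicates 2 and 3, and 9 and 11 without nhr-178 in antimycin replicates 2 and 3; the 4 smaller responses became 2 without WT in DMSO replicate 2, nhr-178 in DMSO replicate 2 or 3, WT in antimycin replicate 3 or nhr-178 in antimycin replicate 2.

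A direct test of both mutants' responses, added after seeing the data, called 633 genes, 457 more positive in nhr-45 and 176 less. Of the 153 genes induced in WT, 30 responded less in nhr-45 than in nhr-178 and 36 more. Among them, 7 of 10 UDP-glucuronosyltransferases, 5 of 13 cytochromes P450 and 1 of 7 glutathione S-transferases responded less and 0 more. Of 19 collagens 16 responded more and 1 less.

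The comparison of nhr-45 with WT in DMSO asks which genes differ without the drug. M199.9 (IV:15127446-15127831) was at 3 ± 0.662 CPM in WT and 237 ± 52.5 CPM in nhr-45 (SD, n = 3), a log2 fold change of 6.28 ± 0.29 (SE, adjusted p = 8.2e-15), and clec-190 beside it (IV:15124931-15126121) rose by 4.14 ± 0.18. K03D3.2, on the same chromosome (IV:16328062-16328619), rose by 6.04 ± 0.44. F57G8.7 and Y49G5A.1, on chromosome V, rose by 6.06 ± 0.34 and 5.30 ± 0.34. The neuropeptide-like gene nlp-25 fell by 2.58 ± 0.23 (adjusted p = 1.1e-08), F55G11.4 by 2.26 ± 0.17 and far-3 by 1.84 ± 0.36.

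Of 40 sperm genes 10 rose, 29 adjusted over the list alone (camera adjusted p = 6.3e-33), with msp-40 higher by 2.74 ± 0.37, and 5 rose without WT in DMSO replicate 2. Of 98 collagens 18 rose and 2 fell, with 36 and 4 adjusted over the list alone (camera adjusted p = 4.7e-22), among them col-142 by 1.75 ± 0.11 and col-96 by 2.57 ± 0.21. Of 8 DAF-16 readout genes 2 fell, 3 adjusted over the list alone (camera adjusted p = 0.0246, but adjusted p = 0.282 with an estimated correlation and 0.309 without WT in DMSO replicate 2; range over the alternatives 0.00412 to 0.309), where dod-3 fell by 1.68 ± 0.33. Cytosolic ribosomal proteins had a median of -0.08 with 0 of 77 called by edgeR (10 at an unadjusted p under 0.05, 0 by DESeq2), also adjusted over the list alone (camera adjusted p = 0.0175, but adjusted p = 0.659 with an estimated correlation). Without WT in DMSO replicate 1 or 3 or nhr-45 in DMSO replicate 1 their adjusted p was 0.0855, 0.0942 and 0.453 (range over the alternatives 6.8e-05 to 0.659). With fry it was 0.266.

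For nhr-45 against WT in DMSO 169 genes were called, 79 higher and 90 lower, and 117 changed at least 2-fold. The count was 100 without WT in DMSO replicate 2, 95 in a fit of the compared groups alone, 262 with no filter, and 171 without both shallow libraries, which belong to other groups.

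In nhr-178 animals without the drug, unc-119, a gene of the nervous system (III:10902641-10908935), was at 13.1 ± 3.72 CPM against 270 ± 8.06 CPM in WT (SD, n = 3), a log2 fold change of -4.35 ± 0.17 (SE, adjusted p = 1.3e-16). It lay between 8.15 and 17 CPM in the 6 nhr-178 libraries of both treatments and between 198 and 354 CPM in the other 12. F56A4.3 (V:2453414-2456147), which lies within 2 Mb of nhr-178, had no count and was at least 58.4-fold lower than in WT. nlp-25 fell by 3.27 ± 0.24 (adjusted p = 7.8e-10) and the collagen gene col-142 by 1.76 ± 0.12 (adjusted p = 4.9e-11). The mismatch repair gene msh-6 rose by 2.63 ± 0.21 (adjusted p = 2.2e-09), from 10.1 ± 1.13 to 62.3 ± 9.97 CPM, and cpr-1 by 1.03 ± 0.15.

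Of 98 collagens 15 fell and 0 rose, with 19 and 7 adjusted over the list alone (camera adjusted p = 5.7e-05, but adjusted p = 0.115 with an estimated correlation), where col-129 fell by 1.45 ± 0.19. Of 40 sperm genes 6 fell, 12 adjusted over the list alone (camera adjusted p = 2.3e-13, but adjusted p = 0.110 with an estimated correlation), and the median log2 change was -2.33, or -0.89 with genes that had a group at 0 set to their bound. Of 8 DAF-16 readout genes 3 fell, also adjusted over the list alone (camera adjusted p = 0.000457, but adjusted p = 0.110 with an estimated correlation and 0.0614 without WT in DMSO replicate 2; range over the alternatives 5.5e-05 to 0.11), where lea-1, a late embryogenesis abundant protein gene, fell by 1.14 ± 0.12. Of 15 muscle markers 2 fell, 6 adjusted over the list alone (camera adjusted p = 0.000784, but adjusted p = 0.160 with an estimated correlation). Lower collagens numbered 8 and 9 without nhr-178 in DMSO replicates 1 and 3. Lower sperm genes numbered 3 without WT in DMSO replicate 1 or nhr-178 in DMSO replicate 3, 2 without nhr-178 in DMSO replicate 1 and 10 with no filter. Without WT in DMSO replicate 2 or nhr-178 in DMSO replicate 1 or 2, 1 DAF-16 readout fell.

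For nhr-178 against WT in DMSO 126 genes were called, 19 higher and 107 lower, of which 70 changed at least 2-fold, and 124 were called without both shallow libraries, which belong to other groups. The count was 80 without WT in DMSO replicate 1, 63, 69 and 73 without nhr-178 in DMSO replicates 1, 2 and 3, 219 with no filter and 198 by DESeq2.

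In antimycin, nhr-45 animals had lower UDP-glucuronosyltransferase and cytochrome P450 genes and higher collagen, moulting and sperm genes than WT. ugt-9 was lower (log2 fold change -8.42, SE 0.28, adjusted p = 2.8e-18) and so was cyp-33C5 (-9.01, SE 0.45, adjusted p = 6.2e-14), with n = 3 per group and levels of 6.52 ± 2.74 and 0.617 ± 0.871 CPM in nhr-45. col-109 was higher by 4.56 ± 0.24, mlt-8 by 4.24 ± 0.25 and the major sperm protein gene msp-64 by 4.04 ± 0.31. vit-2 fell by 0.89 ± 0.18.

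Of 39 UDP-glucuronosyltransferases 11 were lower and 0 higher, also adjusted over the list alone (camera adjusted p = 8.1e-11). Their median was -0.09, or 0.05 without WT in antimycin replicate 2, and their mean -0.97. Of 32 cytochromes P450 13 were lower and 1 higher, with 16 and 3 adjusted over the list alone (camera adjusted p = 7.2e-11), and of 29 glutathione S-transferases 7 and 1, with 8 and 1 adjusted over the list alone (camera adjusted p = 0.00123). In the same libraries 74 of 98 collagens were higher and 3 lower, with 76 and 6 adjusted over the list alone (camera adjusted p = 3.8e-88). So were 15 of 16 moulting genes (camera adjusted p = 7.5e-16), 39 of 40 sperm genes (camera adjusted p = 3.0e-42), both also adjusted over the list alone, and 6 of 10 hypodermis markers, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.1e-12). Muscle and neuron markers, of other tissues, had medians of 0.34 and 0.38, and the intestine markers 0.22, and these 3 lists did not pass camera.

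In the same comparison vitellogenins were lower in nhr-45 in 5 of 6 cases, also adjusted over the list alone (camera adjusted p = 2.2e-05, but adjusted p = 0.0758 with an estimated correlation), and oocyte and eggshell genes in 9 of 19, 11 adjusted over the list alone (camera adjusted p = 5.3e-05, but adjusted p = 0.0927 with an estimated correlation). These 9 became 5 without WT in antimycin replicate 2 or nhr-45 in antimycin replicate 3, and 4 without both shallow libraries. Germline genes fell in 2 of 17 cases, also adjusted over the list alone, where pgl-3, a germ granule gene, fell by 0.61 ± 0.15 (camera adjusted p = 0.0236, but adjusted p = 0.203 with an estimated correlation and 0.0691 with the stricter filter; range over the alternatives 0.000105 to 0.203). Propionate shunt genes fell in 4 of 5, also adjusted over the list alone, but in 1 without WT in antimycin replicate 2 or nhr-45 in antimycin replicate 3 (camera adjusted p = 0.0105, but adjusted p = 0.28 with an estimated correlation), and heat shock genes in 2 of 9, 5 adjusted over the list alone (camera adjusted p = 0.0236, but adjusted p = 0.107 with an estimated correlation). Peroxisomal oxidation genes fell in 3 of 11, also adjusted over the list alone (camera adjusted p = 0.0331, but adjusted p = 0.107 with an estimated correlation). Their adjusted p was 0.053 without WT in antimycin replicate 3, 0.0628 without nhr-45 in antimycin replicate 1 and 0.123 with the stricter filter (range over the alternatives 0.00067 to 0.123).

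For nhr-45 against WT in antimycin 1654 genes were called, 1174 higher and 480 lower, of which 1042 changed at least 2-fold. Without both shallow libraries, 1 in each of these groups, 1356 were called.

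**Figure D4:**
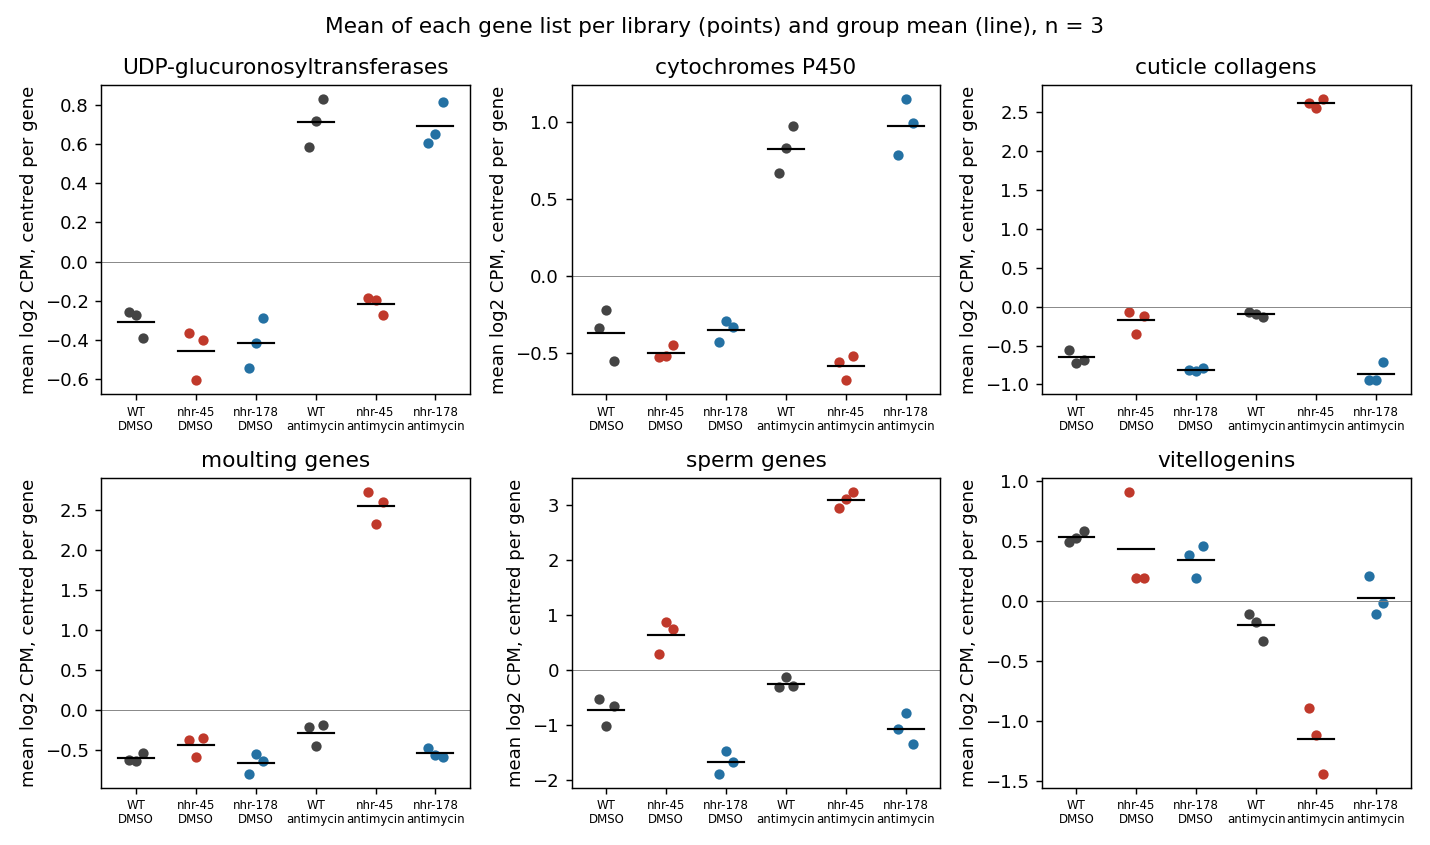
Mean over the genes of 6 lists of log2 CPM, centred per gene, in each library (points) with the group mean (line), n = 3 per group. In nhr-45 in antimycin the collagen, moulting and sperm lists lie highest and the vitellogenin list lowest, and the UDP-glucuronosyltransferase and cytochrome P450 lists lie highest in WT and nhr-178 in antimycin.

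In antimycin, nhr-178 animals had lower collagen, heat shock and muscle genes than WT. unc-54 was at 905 ± 172 CPM against 4323 ± 559 CPM in WT (SD, n = 3), a log2 fold change of -2.26 ± 0.19 (SE, adjusted p = 3.3e-09). unc-119 fell by 5.21 ± 0.17 (adjusted p = 3.7e-18), col-81 by 2.72 ± 0.23 and hsp-16.2 by 1.92 ± 0.31. The aspartic protease gene asp-12 rose by 4.62 ± 0.47 (adjusted p = 1.3e-07), from 0.680 ± 0.411 to 16.5 ± 1.99 CPM, and the thaumatin-like gene thn-1 by 2.69 ± 0.48.

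Of 98 collagens 30 fell and 2 rose, with 46 and 2 adjusted over the list alone (camera adjusted p = 1.9e-31), of 9 heat shock genes 4 fell, also adjusted over the list alone (camera adjusted p = 4.6e-05), and of 15 muscle markers 4 fell, 6 adjusted over the list alone (camera adjusted p = 1.6e-06). Without nhr-178 in antimycin replicate 2, 19 collagens fell, and 2 muscle markers fell without WT in antimycin replicate 3 and 1 without nhr-178 in antimycin replicate 1 or 3. Propionate shunt genes fell in 3 of 5 cases, 5 adjusted over the list alone, sperm genes in 6 of 40, 9 adjusted over the list alone, and hypodermis markers in 2 of 10, 5 adjusted over the list alone. Their camera adjusted p of 3.2e-06, 4.5e-08 and 5.6e-05 became adjusted p = 0.068, 0.105 and 0.0643 with an estimated correlation, and 1 shunt gene fell without WT in antimycin replicate 2. The median of the sperm genes was -1.4, or -1.02 with genes that had a group at 0 set to their bound. Pathogen response genes rose in 2 of 19 cases, 4 adjusted over the list alone, with the lysozyme gene lys-2 higher by 0.80 ± 0.13 (camera adjusted p = 0.00417, but adjusted p = 0.0837 with an estimated correlation).

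DAF-16 readout genes fell in 3 of 8 cases in nhr-178 in antimycin, with 4 lower and 1 higher adjusted over the list alone and a median log2 change of -0.39 (camera adjusted p = 0.018, but adjusted p = 0.175 with an estimated correlation). Their adjusted p was 0.088 without WT in antimycin replicate 2, 0.0801 with no filter and 0.0641 with the stricter filter (range over the alternatives 0.00636 to 0.175), and under these filters the median was 0.01 and -0.02. Without WT in antimycin replicate 2 or nhr-178 in antimycin replicate 2, 1 of them fell. The lysosomal lipases had a median of 0.44 with 0 of 3 called by edgeR (2 at an unadjusted p under 0.05, 1 by DESeq2) and 2 higher adjusted over the list alone (camera adjusted p = 0.0307, but adjusted p = 0.189 with an estimated correlation). Theirs was 0.088 without WT in antimycin replicate 2, 0.0725 without nhr-178 in antimycin replicate 1 and 0.238 with no filter (range over the alternatives 0.00636 to 0.238). Oocyte and eggshell genes had 1 of 19 higher, 3 adjusted over the list alone (camera adjusted p = 0.00748, but adjusted p = 0.268 with an estimated correlation and 0.0516 without nhr-178 in antimycin replicate 1; range over the alternatives 0.000171 to 0.268).

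For nhr-178 against WT in antimycin 399 genes were called, 123 higher and 276 lower, of which 207 changed at least 2-fold, and 356 were called without both shallow libraries. The count was 263 and 261 without WT in antimycin replicates 2 and 3, and 259, 254 and 225 without nhr-178 in antimycin replicates 1, 2 and 3.

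Both mutants were compared with the same WT libraries. In DMSO 18 genes were called lower in both, against 0.877 for independent lists and 0 in each of 20 simulations of unchanged mutants, and 1 was called higher in both (0.137), while 15 that were higher in nhr-45 were lower in nhr-178. In antimycin 33 were higher in both (13.2) and 42 lower (12.1), and 79 higher in nhr-45 were lower in nhr-178. The covariance of the log2 changes was 0.00238 in DMSO against 0.0866 in simulations and -0.108 in antimycin against 0.105, and that of the 2 interactions was 0.172 against 0.194. In the simulations no gene truly differed, so their 0 does not measure what shared WT libraries add to an overlap of real differences. WT groups of 3 libraries cannot be split into parts of at least 2 libraries, so part of any overlap may come from the shared controls.

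The lists that did not pass camera in any of the 9 comparisons were those of the mitochondrial unfolded protein response, the endoplasmic reticulum unfolded protein response, SKN-1 oxidative stress readouts, antioxidant enzymes, the HIF-1 response, short-chain dehydrogenases, flavin-containing monooxygenases, C-type lectins, pals genes, respiratory complexes I, II, IV and V, coenzyme Q synthesis, the tricarboxylic acid cycle, glycolysis, mitochondrial ribosomal proteins, the vitamin B12-dependent propionate route, the methionine cycle, mitochondrial fatty acid oxidation, fatty acid synthesis, the kynurenine pathway, autophagy, nuclear hormone receptors, early embryonic genes and neuron markers. Single members of such lists could still be called. With fry more lists passed than with camera: 26 against 13 for antimycin in WT, 28 against 10 in nhr-45 and 15 against 10 in nhr-178. Fewer passed only for the nhr-178 interaction (3 against 8). A list that did not pass camera was therefore not shown to be unchanged.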

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

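Each value below is a response to antimycin that differed between a mutant and WT by the interaction test of edgeR (n = 3 per group, Benjamini-Hochberg adjusted), a list that passed camera for it, or a count of such genes. Groups of 3 libraries were not tested for a single far library. The tests of germline RNA, of age, of intestinal RNA and of drug action were chosen after the results were seen, and those of the shallow library and of other splits of the libraries before.

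Of the 514 genes called for nhr-45, those with the most reduced induction among genes called in WT with a mean of at least 5 CPM over the 12 libraries were cyp-33C5 (-8.76), ugt-9 (-8.10), ugt-61 (-5.07), cyp-25A2 (-4.97), ugt-1 (-4.65), pgp-9 (-4.27), ugt-2 (-3.37), far-3 (-2.63), ugt-11 (-2.47) and ugt-62 (-2.34), given as interaction log2 values. Induction was larger for F46C5.1 (4.52), col-71 (4.42), mlt-8 (3.95), col-109 (3.89) and Y47D7A.15 (3.86), and the last became 2.47 with an adjusted p of 0.188 without WT in DMSO replicate 1. Repression was smaller or turned for col-10 (6.10), T26H5.9 (3.67), dod-3 (3.61), scl-2 (3.34) and C32H11.4 (2.04). C32H11.4 had an adjusted p of 0.0757 and 0.0681 without WT in DMSO replicates 1 and 3, 0.0633 and 0.0817 without WT in antimycin replicates 1 and 2, 0.0571 without nhr-45 in DMSO replicate 1, and 0.1 and 0.0582 without nhr-45 in antimycin replicates 1 and 3. Of genes induced in WT 27 had a smaller response in nhr-45, and of those repressed 12 did, which fell to 7 without WT in DMSO replicate 1 or 3 or WT in antimycin replicate 3 and rose to 21 with no filter.

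The lists whose nhr-45 response differed had median interaction log2 values of 2.92 for moulting genes, 2.76 for collagens, 2.54 for hypodermis markers, 1.85 for sperm genes, 0.71 for pathogen response genes and 0.64 for DAF-16 readouts. The last had an adjusted p of 0.0616 without WT in DMSO replicate 2. Medians were -0.86 for vitellogenins, -0.68 for cytochromes P450, -0.65 for the propionate shunt, -0.54 for heat shock genes, -0.32 for oocyte and eggshell genes, -0.28 for the germline list and -0.13 for UDP-glucuronosyltransferases (0.02 without nhr-45 in DMSO replicate 1), whose mean was -0.80. With groups at 0 set to the floor of 3 counts, the medians for collagens, sperm genes, pathogen response genes and cytochromes P450 were 2.73, 1.93, 0.71 and -0.59. With an estimated correlation 9 of these 13 lists lost their call: adjusted p was 0.0551 for cytochromes P450, 0.126 for pathogen response genes, DAF-16 readouts, vitellogenins and the germline list, 0.127 for sperm and heat shock genes, 0.163 for oocyte and eggshell genes and 0.191 for the propionate shunt. The transferases lost theirs with no filter (0.0718), and the pathogen response genes with the stricter filter (0.143).

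For nhr-178 29 genes were called, and 4 genes induced and 2 repressed in WT had a smaller response. With no filter 103 genes were called, and 16 of those induced had a smaller response. Reduced induction was seen for ram-2 (-3.36), col-81 (-1.76), Y53F4B.9 (-1.52) and unc-54 (-1.41). Repression was smaller or turned, or the response more positive, for F46C5.1 (3.13), T04D3.8 (1.94), asp-8 (1.4), pfd-2 (1.13), gex-5 (1.08), pho-11 (0.96) and mex-3 (0.83). Single libraries decided several of these calls. The adjusted p of col-81 was 0.0519 to 0.0765 without WT in DMSO replicate 2, nhr-178 in DMSO replicate 2 or 3, WT in antimycin replicate 3 or nhr-178 in antimycin replicate 2. That of gex-5 was 0.0608 to 0.118 without WT in DMSO replicate 1 or 3, nhr-178 in DMSO replicate 1 or 3, WT in antimycin replicate 3 or nhr-178 in antimycin replicate 2 or 3. Leaving out any of the 12 libraries ended the call of Y53F4B.9 (0.0740 to 0.236) except replicate 1 of WT and of nhr-178 in antimycin, of pfd-2 (0.0550 to 0.108) except these and WT in DMSO replicate 3, of pho-11 (0.0605 to 0.144) except WT in DMSO replicate 2 and WT in antimycin replicate 1, and of mex-3 (0.0647 to 0.166) except WT in antimycin replicate 1 and nhr-178 in DMSO replicate 2.

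List medians of the nhr-178 interaction were 0.96 for sperm genes, 0.59 for pathogen response genes, 0.58 for lysosomal lipases, 0.42 for vitellogenins, -0.10 for cytosolic ribosomal proteins, -0.15 for hypodermis markers, -0.75 for the propionate shunt and -0.81 for collagens. With groups at 0 set to the floor of 3 counts, the medians for sperm, pathogen response and collagen genes were 0.20, 0.40 and -0.85. The calls of the sperm, lipase, vitellogenin, ribosomal and hypodermis lists each ended without several single libraries, with adjusted p up to 0.273, 0.126, 0.206, 0.379 and 0.26. With an estimated correlation 6 of these 8 lists lost their call, these 5 with adjusted p = 0.577, 0.394, 0.547, 0.694 and 0.394 and the propionate shunt with 0.0536. With no filter the sperm, lipase and vitellogenin lists had 0.1, 0.532 and 0.0613.

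In nhr-45 in antimycin against WT in antimycin, the collagen list had a median log2 change of 3.94 and the moulting list of 3.42, while vitellogenins had -0.88 (adjusted p = 0.0758 with an estimated correlation). Without the shallow nhr-45 library the collagen median was 3.95, which argues against that library as the cause. A smaller share of germline RNA would raise every somatic tissue alike, and the larger of the upper quartiles of the neuron and muscle lists was 0.81. It lay below the lower quartile of the moulting genes, 2.96, which argues against such a share for these genes. It also lay below the median of the collagens, though not below their lower quartile of 0.62. The bound for the collagens was first that lower quartile, which was not met, and was changed to their median afterwards. With the changed bound, such a share is argued against only as the cause of the collagens' median rise. Animals younger at collection, through a delay from genotype and drug together or the time of collection, stay open: the moulting and yolk genes that would test it are those that show the pattern, so their medians decide nothing. Sperm genes, higher in 39 of 40 cases in the same comparison, were not used to test it.

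The 10 UDP-glucuronosyltransferases induced in WT had a median of -3.43 in nhr-45 against WT in antimycin, and cytochromes P450 were lower as well. Less intestinal RNA in these libraries is argued against, since the lower quartile of the intestine markers, -0.23, lay above the upper quartile of those transferases, -2.49. A weaker action of the drug in nhr-45 animals stays open: 101 other genes induced in WT, outside the detoxification and collagen lists, had a median response of 1.49 in nhr-45, against 2.27 in WT and 1.88 in nhr-178. Without the 11 of them with at most 3 counts in each nhr-45 group, and with 1 at its bound, it was 1.71, and these values lie on either side of a bound of that test. A need for NHR-45 in the induction of these genes, the difference the design names, may account for the pattern too and was not tested apart from that. Animals younger at collection were not tested as a cause of this pattern either.

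Splits of the libraries give as many calls as the real groups in 7 of 100 drawn for each interaction, the real one included, with a highest other count of 826 against 514 for nhr-45 and 134 against 29 for nhr-178. The other 6 in each case kept the genotypes of the antimycin libraries together and moved DMSO libraries, so the genotype difference in antimycin entered them, and this count does not decide whether chance can be excluded. For the 7 other comparisons the 10 splits are too few for a share under 0.05, with 1 split as large, the real one. Their real counts were 330, 2585, 297, 169, 126, 1654 and 399, with a highest other count of 2 for nhr-45 against WT in antimycin and of 0 for the rest.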

How the results depend on the processing

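No called gene changed direction under any alternative, and no list did by camera, but the medians of some lists changed sign. That of DAF-16 readouts in nhr-178 against WT in antimycin was 0.0141 with no filter. Leaving out 1 library gave UDP-glucuronosyltransferases a median of -0.124 to 0.0496 in nhr-45 against WT in antimycin, the highest without WT in antimycin replicate 2, and of -0.234 to 0.0156 for the nhr-45 interaction, the highest without nhr-45 in DMSO replicate 1. Leaving out both shallow libraries was added after the data were seen. Of the values given for whole comparisons, 101 stayed within 1.5 times, or 1 jackknife SE for correlations, under alternatives other than leaving out 1 library and 21 moved. For antimycin in WT, antimycin in nhr-45, nhr-178 against WT in DMSO, nhr-45 against WT in antimycin and nhr-178 against WT in antimycin, a minimum fold change of 2 left 193, 1278, 70, 1042 and 207 genes, by counting fewer genes. With no filter on low counts there were 262 calls for nhr-45 and 219 for nhr-178 against WT in DMSO, 103 for the nhr-178 interaction, 16 genes induced in WT with a smaller response in nhr-178 and 21 repressed with a smaller response in nhr-45, and the correlations of responses were 0.121 for WT and nhr-45, 0.121 for WT and nhr-178 and 0.0978 for both mutants. DESeq2 called 198 genes for nhr-178 against WT in DMSO and 72 for its interaction, and 21 repressed genes with a smaller response in nhr-45, as did the fit without both shallow libraries, while no minimum fold gave 19. A fit of only the compared groups called 95 genes for nhr-45 against WT in DMSO, and put 75.0% of the calls for antimycin in nhr-45 higher, against 64.6%. The correlation of WT and nhr-178 was 0.541 with the stricter filter and 0.853 over genes called in WT. Except for the fold minimum, the cause was not tested.

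Leaving out 1 library gave 173 to 314 calls for antimycin in WT, 1836 to 2536 in nhr-45 and 196 to 279 in nhr-178. It gave 100 to 153 for nhr-45 and 63 to 94 for nhr-178 against WT in DMSO, 1320 to 1562 and 225 to 354 in antimycin, and 335 to 506 and 9 to 41 for the interactions. Genes induced in WT numbered 109 to 151, those with a smaller response 24 to 33 in nhr-45 and 2 to 4 in nhr-178, and repressed genes with a smaller response in nhr-45 7 to 17. Each such fit holds fewer samples. Of the list results 580 kept their side of the threshold and the sign of their median and 54 lost the call, and of the named genes 2459 kept it, 329 lost it and 2 gained it. Under the other alternatives these numbers were 515 and 77 for lists, mostly with an estimated correlation, and 2659, 48 and 7 for named genes. The number of genes called in a list moved by over 1.5 times under some alternative for 5 of 13 list results with no gene called, for 14 of 15 with 1 or 2 and for 27 of 57 with more. The stricter filter, which tests fewer genes, called 23 of 24 sperm genes higher for antimycin in nhr-45 and for nhr-45 against WT in antimycin, and 8, 8 and 7 of 15 cytochromes P450 for antimycin in WT, antimycin in nhr-178 and nhr-45 against WT in antimycin.

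With the replicate number as a replicate block, 326, 2563 and 296 genes were called for antimycin in WT, nhr-45 and nhr-178, 170 and 122 for the mutants in DMSO, 1652 and 405 in antimycin, and 490 and 30 for the interactions. The lipase list lost its call for the nhr-178 interaction (adjusted p = 0.0503, over its alternatives 0.0321 to 0.532), as did Y53F4B.9 (0.0633). Deviations of libraries with the same number correlated at -0.0858 to 0.0872 over 45 pairs, 0 of them over 0.1, and 9 of 18 libraries correlated best with their own number, so the numbers do not pair the samples.

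Depth limits what can be seen for weakly expressed genes: nhr-178 itself could not be tested. In simulations 51.1% and 43.1% of responses that differed by a log2 of 1 were recovered for the nhr-45 and nhr-178 interactions, so an uncalled gene was not shown to respond alike.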

Other observations

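The tests of linkage to nhr-178, of neurons, of a variant at unc-119 and of the chromosome II stretch were chosen after the results were seen. Those of linkage to nhr-45 and of extra unc-119 copies were chosen before.

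The genes of this paragraph were chosen after their values were seen. ins-6, an insulin-like peptide gene (II:6000436-6001009), was at 5.78 ± 0.959 CPM in WT in DMSO and 1.53 ± 1.1 CPM in nhr-45 (log2 fold change -1.99 ± 0.42, adjusted p = 0.00882), and at 8.48 ± 1.71 and 0.390 ± 0.236 CPM in antimycin (-4.69 ± 0.57, adjusted p = 6.2e-07; SD of levels, n = 3, SE of changes). cdr-4, of the cadmium-responsive family (V:12407366-12408625), rose in antimycin by 3.53 ± 0.17 in WT (adjusted p = 1.6e-14) and by 1.70 ± 0.19 in nhr-45 (adjusted p = 1.4e-07), with an interaction of -1.82 ± 0.25 (adjusted p = 3.5e-05). nlp-33, an antimicrobial peptide gene of the epidermis, and nlp-25 fell in both mutants in DMSO. In nhr-45 antimycin raised nlp-25 from 6.61 ± 0.729 to 52.6 ± 2.4 CPM, against 39.3 ± 5.65 and 36.2 ± 1.34 CPM in WT, with an interaction of 3.12 ± 0.31 (adjusted p = 1.2e-07). In nhr-178 it was at 4.02 ± 1.08 and 1.67 ± 0.985 CPM.

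Many genotype differences were present in both treatments, which share no library. For nhr-45, 62 genes were higher than WT in both (8.45 for independent lists) and 32 lower (3.93), while 14 were lower in DMSO and higher in antimycin. For nhr-178, 10 were higher in both (0.213) and 69 lower (2.69). Among the latter the neighbouring genes spig-4 and spig-5, singled out after their values were seen, were at 6.01 ± 2.95 and 8.45 ± 2.44 CPM in WT in DMSO and at 0.106 ± 0.0921 and 0.289 ± 0.501 CPM in nhr-178. The interactions shared 7 genes called higher (0.542) and 3 lower (0.168), while 5 called higher for nhr-45 were lower for nhr-178. Simulations of unchanged mutants against the same WT libraries gave 0 shared calls in either direction. With no true difference to call, they do not measure what the shared WT libraries add to the overlap of the interactions. Of common stress readouts in WT, gst-4 had a log2 change with antimycin of 1.07 ± 0.39 (adjusted p = 0.164), sod-3 of 1.08 ± 0.77 (adjusted p = 0.573), acdh-1 of -0.05 ± 0.16 (adjusted p = 0.943) and nhr-57 of -0.12 ± 0.66 (adjusted p = 0.97). In nhr-45 nhr-57 rose by 1.84 ± 0.61 (adjusted p = 0.0299), but its adjusted p was 0.129 and 0.0735 without nhr-45 in DMSO replicates 2 and 3 and 0.0516 and 0.0898 without nhr-45 in antimycin replicates 1 and 3.

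unc-119 was at 13.1 ± 3.72 CPM in nhr-178 and 270 ± 8.06 CPM in WT in DMSO, and low in all 6 nhr-178 libraries. Fewer neurons are argued against, since the neuron list had medians of 0.08 and -0.08 in nhr-178 in DMSO and antimycin and its lower quartiles reached only -0.63. A variant of the nhr-178 strain at unc-119 itself may account for the pattern, as a hypothesis: the 13 tested genes within 50 kb had a median log2 change of 0.13 (-0.18 to 0.93), and 0 of them were called. Extra copies of unc-119 in the other strains stay open: the bound set beforehand, that unc-119 lies within the range of the neuron list in WT, was met, with snb-1 at 331 ± 28.9 CPM, but another gene's level sets no limit on that of an extra copy, and unc-119 lay above 11 of the 12 neuron genes, whose median was 12 CPM. The labels give WT as N2, which argues against a transgene there.

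Variants linked to the mutant alleles are a hypothesis for differences present in both treatments. Of the 79 such genes in nhr-178, 7.59% lay within 2 Mb of nhr-178 (6 genes: F56A4.3, F59A7.2, T03D3.5, cnc-4, dod-3 and sti-1), against 2.17% of tested genes (Fisher's exact test, two-sided p = 0.00725). Of these 6, sti-1 was also lower in nhr-45 in DMSO and antimycin (-0.98 and -1.51), against -0.89 and -1.07 in nhr-178, and dod-3 was lower in nhr-45 in DMSO (-1.68), which linkage to nhr-178 does not account for. Linkage may account for some of the others but not for most of the 79, nor for unc-119 on chromosome III. Of the 94 in nhr-45, 1.06% lay within 2 Mb of nhr-45 (col-169 alone), against 3.50% of tested genes (Fisher's exact test, p = 0.265).

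A stretch of 20 expressed genes on chromosome II (II:6951526-7075511, ceh-38 to kat-1) had the lowest median of 7398 such windows in nhr-178 in DMSO, -0.54 with 18 genes lower, and in antimycin it was tied for the lowest, at -0.52 with 16 lower. In nhr-45 its medians were 0.14 and -0.02. It holds sod-1, a cytosolic superoxide dismutase gene (-1.14 and -1.21 in DMSO and antimycin), art-1 (-0.97 and -0.92), cth-2 (-0.93 and -1.08) and kars-1 (-0.65 and -0.45), each called in both treatments. A copy number difference of this stretch between the strains may account for that, as a hypothesis that genome sequence could test; regulation shared by these neighbours was not tested.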
